A study of Shewanella oneidensis with 16 samples.

How the data were processed

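Shewanella oneidensis MR-1 was grown in a continuous-flow bioreactor at 30 °C, pH 7 and 200 rpm, per the labels' protocols. Cells (10 mL per sample) went into cold phenol and ethanol, RNA was extracted with hot phenol and treated with DNase I, rRNA was removed with Ribo-Zero, and Illumina libraries were made. Per the submitters' processing notes CASAVA 1.5, Trimmomatic, Bowtie, HTSeq and DESeq2 were used. The genome build, annotation version, aligner settings and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts of reads per gene, 1 file per library, with the HTSeq summary lines at the end.

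The 16 files list the same 4555 genes in the same order. A file sums to 31939700 to 39060800 reads, of which 44.7 to 46.2% were assigned to genes. Reads that HTSeq assigned to no gene made up 52.3 to 53.7% of the aligned reads and ambiguous reads 0.473 to 0.598%. The reads not aligned were 1.30 to 3.53% of the total. No read was counted as aligned to several places or as of low quality, so how multi-mapped reads were treated is not known and counts of repeated genes (rRNA genes, transposases) are uncertain. As the strand setting is unknown, counts of overlapping or antisense genes are uncertain too. For the same reason, reads assigned to no gene need not lie outside genes. Gene names come from the table of assembly ASM14616v2: 4399 of the 4555 locus tags matched it, and 1236 carried a gene symbol. Genes without a symbol there keep their locus tag. rRNA genes (28) took 2.69 to 7.45% of the counts in genes and tRNA genes (103) 0.262 to 0.476%. The prophage regions took 0.116 to 0.176% (lambdaSo), 0.0953 to 0.159% (muSo1) and 0.122 to 0.184% (muSo2).

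Libraries were grouped by the stated time, with 3 controls, 2 libraries at 0 min, 3 at 15, 30 and 45 min and 2 at 60 min. In R 4.3.3, genes were kept by filterByExpr with the groups (4496 kept, 59 removed) and scaled by TMM, with factors of 0.817 (15 min replicate 3) to 1.25 (control replicate 2). The controls had factors of 1.16 to 1.25 and the other libraries 0.817 to 1.06. Small changes against the control, and their split into higher and lower, therefore depend on this scaling. Differences were tested with the edgeR 4.0.16 quasi-likelihood F-test (estimateDisp, glmQLFit with robust = TRUE) in 1 fit of the 16 libraries and 6 groups without a block. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The common biological coefficient of variation was 20.0%. Comparisons were each time against the control, each time against the one before, 60 against 0 min, and the 6 groups at once. A linear trend over minutes was fitted to the 13 libraries from 0 to 60 min (4492 genes). The ± after a fold change is its standard error. That after a CPM value is the SD between libraries of TMM-scaled CPM. Principal components and distances used log2 CPM with a prior count of 2.

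Genes to be named were chosen by a rule: for each time against the control the 8 highest and 8 lowest fold changes among called genes with a mean log2 CPM of at least 4 and every library of the time on the same side of every control. For steps between times the number was 3 per direction and for the trend 5. A further 26 key genes were named whatever their result, and up to 4 examples per list. The 30 gene lists, by locus tag, were written from general knowledge of the genome, and 564 of their 575 members are in the files. The list called ribosomal holds SO_0219, which the reference names nusG. Lists were tested with camera (limma 3.58.1), which asks whether the genes of a list moved further than other genes, with its preset correlation of 0.01 between genes and adjustment over the lists of at least 3 genes. The comparisons, tests, lists, named-gene rule and alternatives were chosen before the data were examined, apart from those said in the closing section to have been added.

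Alternatives were RLE scaling, no count filter, the DESeq2 1.42.0 Wald or likelihood-ratio test, the replicate number as a block, removal of rRNA and tRNA genes, robust = FALSE, a fit of only the 2 groups compared, and each library left out in turn. When a library of a group of 2 is left out, the remaining 1 is tested with the spread of the other groups. For lists, camera with a correlation estimated per list and fry were run. Overlap between times was set against n1 × n2 / N and against 20 simulations of unchanged groups that share the controls.

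The whole procedure was tested on simulated data with the same group sizes and spread, in which 200 of 4491 to 4495 tested genes were changed (67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold). Against the control, it recovered 20.9, 67.2 and 95.5% of them (1.5-, 2- and 4-fold) at 0 min, 40.3, 77.6 and 100.0% at 15 min, 32.8, 77.6 and 100.0% at 30 min, 35.8, 73.1 and 97.0% at 45 min and 26.9, 64.2 and 95.5% at 60 min. Between times it recovered 19.4, 68.7 and 95.5% (15 against 0 min), 35.8, 73.1 and 98.5% (30 against 15), 32.8, 71.6 and 97.0% (45 against 30), 22.4, 68.7 and 95.5% (60 against 45) and 11.9, 53.7 and 95.5% (60 against 0). The trend recovered 20.9, 73.1 and 98.5%. In the test of the 6 groups at once 10.4 to 22.4, 55.2 to 70.1 and 93.9 to 100.0% were recovered, depending on the time changed. Between 2 and 12 unchanged genes were called per comparison. Changed genes were drawn at random and libraries independently, so no replicate stood apart as in the data. These shares therefore do not give the recovery for genes whose libraries differ widely. SO_A0153 at 0 min, for example, rose by 5.09 ± 1.39 with an edgeR adjusted p of only 0.0459. Few or no calls between times thus do not show that no large change occurred. In a simulation of 30 min against the control (4495 genes), 3 lists raised 1.5-fold were all called by camera, with the preset and with an estimated correlation, and no other list was. Genes were drawn independently there, so this cannot show how either form of camera fares when the genes of a list vary together. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.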

Results

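RNA was sequenced from Shewanella oneidensis MR-1, a bacterium that can respire on metals outside the cell, in a bioreactor fed at a dilution rate of 0.05 per hour. Control libraries were taken after 48 h of continuous feeding at a dissolved oxygen tension of 20%. The oxygen regulation was then switched off, dissolved oxygen became unmeasurable within 3 to 5 min, and that moment is 0 min; sampling went on to 60 min with air still supplied. The 16 libraries form 6 groups: 3 controls, 2 at 0 min, 3 each at 15, 30 and 45 min, and 2 at 60 min. Each library holds 14494600 to 17883700 reads assigned to genes, and 3 reads correspond to 0.168 to 0.207 in counts-per-million units (CPM). The RNA ssrA took 9.70 to 12.1% of these reads, SO_m009 7.38 to 17.5% (highest in control replicate 1) and rnpB 1.87 to 4.09%. Nothing states that the libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Fold changes are log2 ± SE from edgeR, and the largest are taken among genes with a mean log2 CPM of at least 4 and all libraries of a time on 1 side of all controls. Adjusted p-values are Benjamini-Hochberg values over the 4496 genes tested unless a list is named.

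The control libraries lay apart from all others on the first principal component, which held 66.6% of the variance, at -41.5, -39.8 and -39.6. The library labelled 0 min replicate 2 (5.74) lay beside 15 min replicate 1 (5.57) and near 30 min replicates 1 and 2 (6.93 and 7.07). The library labelled 15 min replicate 2 (-13.9) lay beside 0 min replicate 1 (-10.8). Replicate 3 stood away from the other replicates of its time: at 15 min it lay at 32.5, and its distance from the control mean was 75.0, against 50.1 for replicate 1. At 30 and 45 min its distances were 65.8 and 60.6, against 50.7 to 53.4 for replicates 1 and 2, and at 60 min 56.1 against 55.2. In replicate 3 minus replicate 1, the median differences at 15, 30, 45 and 60 min were -1.77, -1.20, -0.86 and -0.28 for the cbb3 oxidase genes. For the heat shock and protease genes they were 1.51, 0.02, -1.02 and -1.45.

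**Figure D1:**
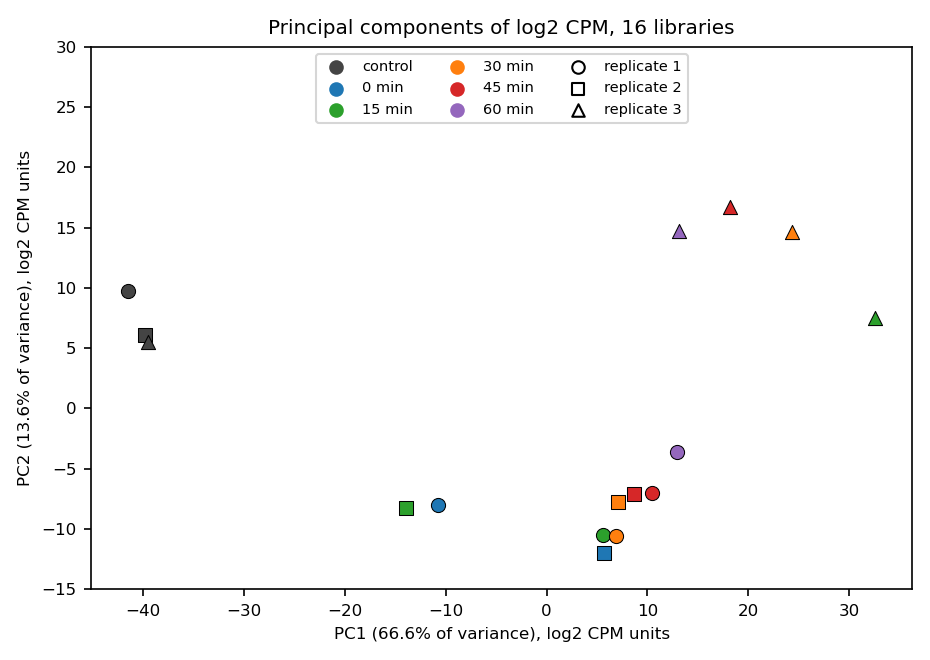
Principal components 1 (66.6% of variance) and 2 (13.6%) of log2 CPM for 16 libraries; each point is 1 library, colours are the 6 groups and symbols the replicate numbers. The 3 controls lie at -41.5 to -39.6 on component 1 and replicate 3 at 15 min at 32.5.

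**Figure D2:**
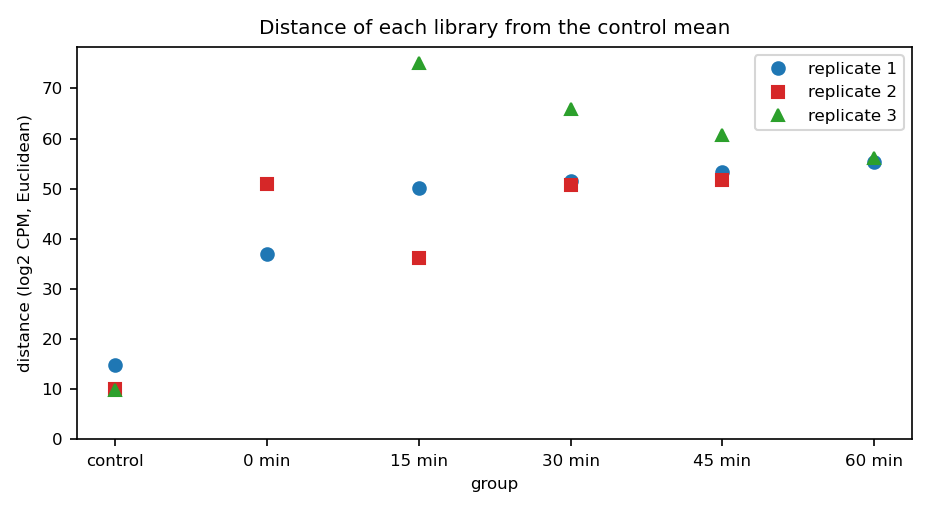
Euclidean distance in log2 CPM of each of the 16 libraries (points, symbols by replicate number) from the mean of the 3 controls, by group. Replicate 3 reaches 75.0 at 15 min and 56.1 at 60 min, and the library labelled 15 min replicate 2 lies at 36.2 below the library labelled 0 min replicate 2 at 51.0.

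Each time was compared with the control to ask how gene expression changed as oxygen, the electron acceptor, became limiting in the chemostat. At 0 min (2 libraries against 3) the largest rises were in SO_A0155 (6.15 ± 0.96), SO_4512 (5.95 ± 0.54), SO_A0154 (5.91 ± 1.04) and ompW, which encodes an outer membrane protein (5.49 ± 0.30, adjusted p = 2.78e-07). Mean expression of ompW went from 154 ± 0.721 to 6930.3 ± 1458 CPM (± SD). The hydrogenase genes hyaA and hyaB rose by 5.15 ± 0.45 and 4.92 ± 0.67, and cymA, which encodes a cytochrome that passes electrons out of the quinone pool, by 1.91 ± 0.25. The outer membrane cytochrome genes mtrC and omcA rose by 2.18 ± 0.40 and 1.93 ± 0.39, and SO_3286 by 2.09 ± 0.27. Falls were smaller, the largest in SO_2850 (-1.56 ± 0.22), SO_0744 (-1.39 ± 0.17) and SO_3987 (-1.35 ± 0.18). By edgeR, 299 genes changed, 258 higher and 41 lower, and 201 of the higher and 10 of the lower moved at least 2-fold. Without the library labelled 0 min replicate 2 the count was 112, and mtrC (1.78, adjusted p = 0.0733) and omcA (1.48, adjusted p = 0.161) no longer passed. Leaving out 15 min replicate 3 gave 520 genes, a fit of only these 2 groups 503 (406 higher, 97 lower) and DESeq2 543 (410 higher, 133 lower).

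Several genes named in advance did not pass at 0 min: SO_1776 (1.77 ± 0.57, adjusted p = 0.0869), the fumarate reductase gene fccA (1.90 ± 0.56, 0.0646), the nitrate reductase gene napA (1.49 ± 0.45, 0.0693) and pflB (1.38 ± 0.45, 0.0947). SO_1776 passed without 0 min replicate 1 (2.34, adjusted p = 0.0457), the library labelled 15 min replicate 2 (1.77, adjusted p = 0.00921) or 15 min replicate 3 (1.78, adjusted p = 0.0320). fccA and napA also passed without the library labelled 15 min replicate 2 (1.90, adjusted p = 0.0163 for fccA; 1.49, adjusted p = 0.0124 for napA). Without 15 min replicate 3 their values were 1.91, adjusted p = 0.00189 (fccA) and 1.5, adjusted p = 0.0132 (napA). pflB passed without 15 min replicate 1 (1.38, adjusted p = 0.0361) or 15 min replicate 3 (1.38, adjusted p = 0.000920).

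At 15 min (3 against 3) SO_A0155 (7.15 ± 0.98), SO_A0154 (6.99 ± 1.06), SO_4512 (6.38 ± 0.53) and SO_A0157 (6.29 ± 0.99) were among the genes furthest above the control. Replicate 3 was the highest library for each of them. SO_A0154 stood at 16973 CPM there, against 5499.2 and 813.1 in replicates 1 and 2. SO_1776, fccA and pflB now passed, at 2.43 ± 0.54, 3.00 ± 0.55 and 2.75 ± 0.44. The cytochrome gene SO_1427 reached 5.37 ± 0.68. Much of these sizes comes from replicate 3 as well. SO_1427 stood at 638.3 CPM there against 122.5 and 89.7 in replicates 1 and 2, and fccA at 25592 against 7286.7 and 4368.9. SO_2850 (-1.63 ± 0.19) and SO_3987 (-1.54 ± 0.16) were among the largest falls, and sodB, which encodes a superoxide dismutase, fell (-1.72 ± 0.47). The sodB call was lost without control replicate 1 (-1.70, adjusted p = 0.0620), control replicate 3 (-1.70, adjusted p = 0.0530), 15 min replicate 1 (-1.79, adjusted p = 0.0528) or 15 min replicate 3 (-1.31, adjusted p = 0.0551). napA passed at 1.75 ± 0.42 but not without 15 min replicate 3 (1.14, adjusted p = 0.0548). A total of 849 genes changed (edgeR), 604 higher and 245 lower, with 342 and 34 at least 2-fold. That count fell to 523 without control replicate 1 and to 488 without 15 min replicate 3. A fit of only these 2 groups called 249 (224 higher, 25 lower), and DESeq2 1148.

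At 30 min (3 against 3) SO_A0155 (6.82 ± 0.97), SO_A0154 (6.42 ± 1.04), SO_A0157 (6.11 ± 0.98), SO_4512 (6.08 ± 0.53) and hyaB (5.66 ± 0.67) were among the largest rises. The largest fall was in SO_2045 (-3.06 ± 0.63, adjusted p = 0.00453), followed by the aa3 oxidase gene coxB (-2.49 ± 0.49, 0.00377). The oxidase subunit gene ctaD, not past the threshold at 0 min (-0.88) or 15 min (-1.03), fell (-2.27 ± 0.61). At 15 min it passed without the library labelled 15 min replicate 2 (-2.31, adjusted p = 0.00246), and its 30 min call was lost without 30 min replicate 2 (-2.35, adjusted p = 0.0518) or 3 (-2.05, adjusted p = 0.0830). mtrC, omcA and cymA stood at 2.60 ± 0.38, 2.38 ± 0.37 and 2.10 ± 0.24. The nitrite reductase gene nrfA, not past the threshold at 0 min (1.08) or 15 min (1.22, except in 3 of 16 fits, without the library labelled 15 min replicate 2, 30 min replicate 3 or 45 min replicate 3, adjusted p down to 0.0120), rose by 1.64 ± 0.42, a call lost without control replicate 2 (1.55, adjusted p = 0.0545) or 30 min replicate 3 (1.16, adjusted p = 0.0728). edgeR called 964 genes, 617 higher and 347 lower, of which 333 and 81 moved at least 2-fold. The number was 587 without control replicate 1 and 571 without 30 min replicate 3.

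At 45 min (3 against 3) the order was SO_A0155 (6.29 ± 0.95), SO_4512 (6.03 ± 0.53), SO_A0154 (5.87 ± 1.01), hyaB (5.68 ± 0.67) and ompW (5.63 ± 0.30). SO_2045 (-3.43 ± 0.64) and coxB (-2.49 ± 0.49) were lowest, with SO_2046 at -2.0 ± 0.39. fccA (2.77 ± 0.54), napA (2.30 ± 0.43), nrfA (1.84 ± 0.42) and pflB (1.76 ± 0.42) were all higher than in the control. ctaD was at -2.34 ± 0.61, a call lost without 45 min replicate 3 (-2.22, adjusted p = 0.0640). At this time 1051 genes passed by edgeR, the most of any time, 646 higher and 405 lower, and 333 and 92 of them at least 2-fold. Leaving out control replicate 1 gave 650 and leaving out 45 min replicate 3 gave 648.

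At 60 min (2 against 3) SO_A0155 (6.04 ± 0.96), SO_4512 (5.88 ± 0.54), hyaB (5.68 ± 0.69) and ompW (5.66 ± 0.30) were highest, and ompW stood at 7803 ± 229.8 CPM. mtrC (2.74 ± 0.40, adjusted p = 0.000569) and omcA (2.58 ± 0.40, 0.000809) had their largest values here. The largest fall was SO_2045 at -3.88 ± 0.77, which did not pass without 60 min replicate 3 (-3.69, adjusted p = 0.0606). coxB stood at -2.56 ± 0.58 and lost its call without 60 min replicate 1 (-2.50, adjusted p = 0.0762) or 3 (-2.63, adjusted p = 0.0755). nrfA (2.02 ± 0.45) was lost without 60 min replicate 3 (1.76, adjusted p = 0.0734). pflB (1.90 ± 0.46) was lost without 60 min replicate 1 (1.96, adjusted p = 0.0522) or 3 (1.84, adjusted p = 0.0704). ctaD (-2.44 ± 0.72) lost its call in 5 of 16 fits, without any 1 control (-2.57, -2.41 and -2.35, adjusted p = 0.0555, 0.0649 and 0.0695) or either 60 min library (-2.45, adjusted p = 0.139 and -2.45, adjusted p = 0.175). edgeR found 839 genes changed, 568 higher and 271 lower, with 334 and 70 at least 2-fold. The count without control replicate 1 was 551, without control replicate 2 558, without 15 min replicate 3 1340, without 60 min replicate 1 346 and without 60 min replicate 3 350. A fit of only these 2 groups gave 1338 (768 higher, 570 lower) and DESeq2 1319 (776 higher, 543 lower).

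**Figure D3:**
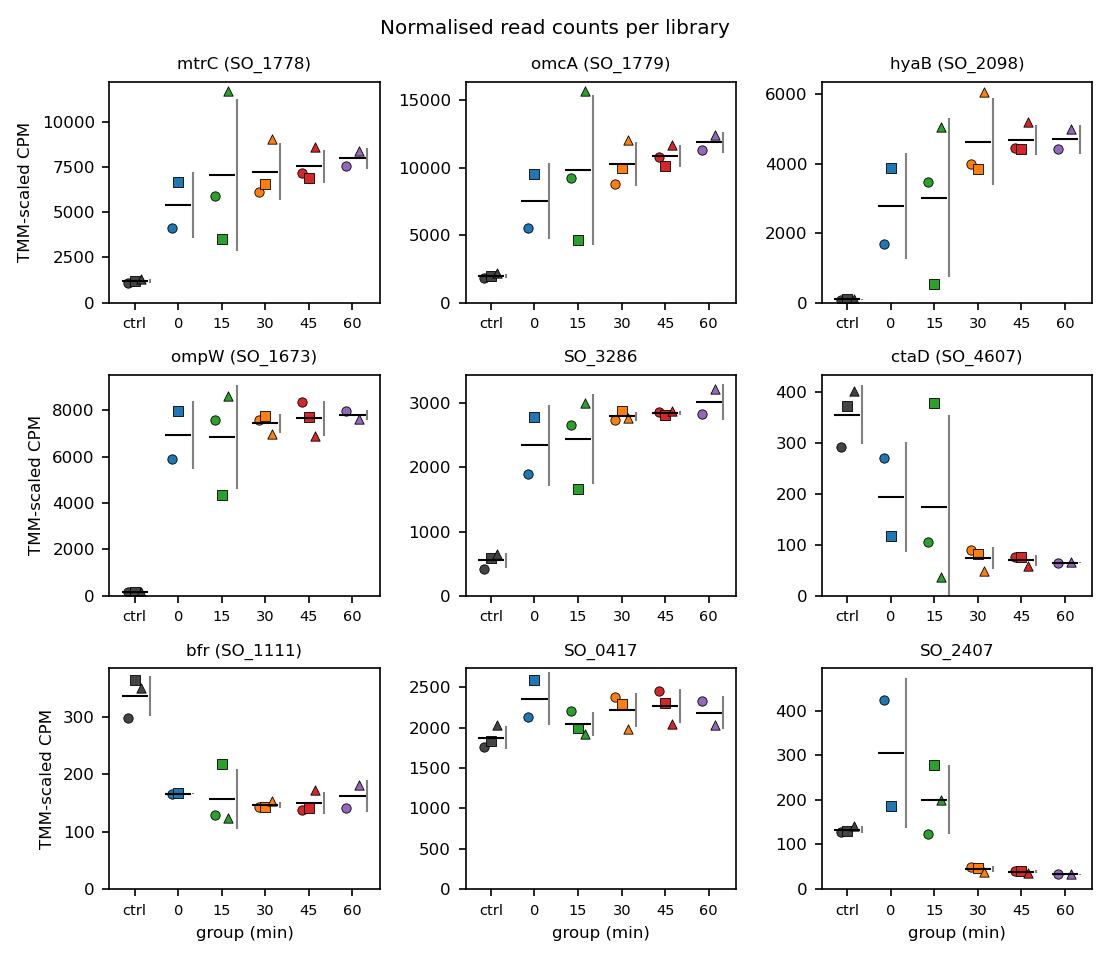
TMM-scaled CPM of 9 genes in each library (points, symbols by replicate number) over the control and the 5 times, with the group mean (black line) and SD (grey line, drawn down to 0 at most). ompW rises from a mean of 154 ± 0.721 CPM in the control to 7803 ± 229.8 at 60 min, while SO_2407 goes from 134 ± 7.30 to 33.5 ± 1.04 (mean ± SD).

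Lists of genes fixed in advance were then tested as groups. In the list for Mtr and Omc extracellular electron transfer (8 genes), 4 members rose at 0 min and 5 at each later time, with list medians of 1.84, 2.27, 2.24, 2.25 and 2.35 in order of time. mtrA rose by 2.45, 2.63, 2.65 and 2.77 from 15 min on, and cymA by 1.91, 2.23, 2.10, 2.05 and 2.12 over the 5 times. The gene SO_1776 rose by 2.43, 2.67, 2.72 and 2.82 from 15 min on. At 30 min 1 member fell, and adjusted over the list alone 5 rose at every time while 0, 1, 3, 1 and 0 fell. The mtrA call at 0 min (1.96 ± 0.50) was lost without control replicate 1 (1.91, adjusted p = 0.114), control replicate 2 (1.95, adjusted p = 0.0995), control replicate 3 (2.03, adjusted p = 0.0809) or the library labelled 0 min replicate 2 (1.31, adjusted p = 0.458). The camera test called the list higher at all times (adjusted p = 0.00154, 0.00879, 0.00867, 0.00492 and 0.00376), and at no time with an estimated correlation (adjusted p = 0.180, 0.298, 0.188, 0.247 and 0.278 with an estimated correlation).

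The cytochrome c maturation genes, which attach heme to these cytochromes, rose as a block: 5 of 10 passed at 0 min and all 10 from 15 min on, and 10 at every time adjusted over the list alone. ccmA rose by 1.91, 2.40, 2.23, 2.11 and 2.12 and ccmB by 1.74, 2.21, 2.11, 2.01 and 2.03 over the 5 times. List medians were 1.26, 1.54, 1.60, 1.53 and 1.44. camera gave adjusted p = 3.44e-10, 3.54e-11, 5.67e-11, 1.28e-09 and 1.11e-08, against adjusted p = 0.185, 0.298, 0.188, 0.247 and 0.307 with an estimated correlation. Of the 43 c-type cytochrome genes as a whole, 6, 13, 15, 16 and 15 rose and 0, 4, 6, 6 and 4 fell in order of time (8, 14, 16, 16 and 15 and 0, 5, 9, 9 and 7 over the list alone). SO_1427 was the furthest above control (4.03, 5.37, 4.66, 4.70 and 4.80) and coxB the lowest at 60 min. This list was called only at 0 min (adjusted p = 0.0358, and adjusted p = 0.185 with an estimated correlation). That call was lost without control replicate 1 (0.0777) or the library labelled 0 min replicate 2 (0.0690), and at the later times camera gave 0.245, 0.180, 0.0999 and 0.149. Without 15 min replicate 3 the list was called at 45 min too (0.0468).

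Of 26 genes for anaerobic terminal reductases, 2, 16, 17, 17 and 18 rose in order of time and none fell, with medians of 1.21, 1.53, 1.80, 2.02 and 2.16. Adjusted over the list alone, 12, 17, 17, 18 and 18 rose. hcp rose by 2.24, 2.65, 2.62, 2.59 and 2.58 and SO_1427 by 4.03, 5.37, 4.66, 4.70 and 4.80 over the 5 times. fccA rose by 3.00, 2.65, 2.77 and 2.86 and napA by 1.75, 2.14, 2.30 and 2.36 from 15 min on, while torA, for trimethylamine N-oxide, never passed (-0.05, -0.10, -0.01, -0.01 and 0.16). SO_1429 rose by 4.60, 4.17, 4.16 and 4.23 from 15 min on, and its calls were lost in 3, 4, 3 and 5 of 16 fits (adjusted p up to 0.0727, 0.0658, 0.0628 and 0.0744). Those fits left out control replicate 1, 2 or 3, 15 min replicate 3, 30 min replicate 3 or a 60 min library. camera called the list at every time (adjusted p = 0.000163, 7.77e-05, 1.46e-06, 5.69e-07 and 4.18e-08; adjusted p = 0.585, 0.601, 0.447, 0.421 and 0.389 with an estimated correlation).

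The terminal oxidases for oxygen went different ways. All 3 bd oxidase genes rose from 15 min on, and 2 passed at 0 min (3 over the list alone). SO_3286 rose by 2.09, 2.15, 2.34, 2.37 and 2.45 and cydB by 1.91, 1.99, 2.33, 2.34 and 2.41 over the 5 times, though cydB at 0 min was lost without the library labelled 0 min replicate 2 (1.38, adjusted p = 0.20). List medians were 1.91, 1.99, 2.33, 2.34 and 2.41 and camera adjusted p = 9.93e-05, 0.000708, 0.000110, 0.000103 and 8.14e-05 (adjusted p = 0.185, 0.298, 0.188, 0.247 and 0.278 with an estimated correlation). In the aa3 oxidase list 0, 1, 4, 4 and 4 of 4 genes fell in order of time, the same numbers over the list alone, and medians went from -0.72 at 0 min to -2.40 at 60 min. coxB fell at 30, 45 and 60 min (-2.49, -2.49 and -2.56), and at 15 min (-1.53 ± 0.48) in a call lost in 12 of 16 fits and kept only without 0 min replicate 1, the library labelled 0 min replicate 2, the library labelled 15 min replicate 2 or 30 min replicate 3. camera called this list from 15 min on (adjusted p = 0.145, 0.0494, 0.00272, 0.00319 and 0.00376 over the 5 times; adjusted p = 0.670, 0.601, 0.418, 0.421 and 0.404 with an estimated correlation). The 15 min call of the list was lost in 10 of 16 fits, up to 0.158 without 15 min replicate 3, and kept without control replicate 1, 0 min replicate 1, the library labelled 0 min replicate 2, the library labelled 15 min replicate 2 or 45 min replicate 1 or 2. At 0 min it was called without the library labelled 15 min replicate 2 (0.0403).

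None of the 4 cbb3 oxidase genes passed at any time, with medians of 1.06, 0.48, 0.85, 0.89 and 0.75 (camera adjusted p = 0.0797, 0.753, 0.268, 0.267 and 0.345). ccoN stood at 1.14, 0.53, 0.93, 0.94 and 0.83, and at 45 min it passed in 1 of 16 fits (adjusted p = 0.0497). Adjusted over the list alone, all 4 rose at 0 min and none later. camera called the cbb3 list higher at 0 min without the library labelled 0 min replicate 2 (0.0445) or 30 min replicate 3 (0.0406), and at 30 min without 30 min replicate 3 (0.0458). Without all 5 libraries of replicate 3, which lay below replicate 1 in these genes from 15 to 60 min, it was called higher at 0, 15, 30 and 45 min (0.00243, 0.0189, 0.00237 and 0.00523). In the bc1 complex list (3 genes) petA alone fell, at 15 min (-1.36 ± 0.42), a call lost in 10 of 16 fits (adjusted p up to 0.0922) and kept without 0 min replicate 1, 15 min replicate 3, the library labelled 15 min replicate 2, 30 min replicate 2 or 3 or 45 min replicate 3. It fell over the list alone too. List medians were -0.41, -0.86, -0.94, -0.82 and -0.90 (camera 0.342, 0.123, 0.180, 0.228 and 0.212, and 0.0497 at 15 min without control replicate 1).

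Hydrogenase genes rose at every time: 11, 14, 13, 13 and 14 of 18 passed in order of time (13, 14, 15, 15 and 14 over the list alone) and none fell. hyaA rose by 5.15, 5.20, 5.56, 5.58 and 5.57 and hyaB by 4.92, 5.04, 5.66, 5.68 and 5.68 over the 5 times. The maturation gene hypB rose by 3.29, 3.54, 3.63, 3.60 and 3.59. hydA, of the other hydrogenase, rose by 1.40, 1.60, 1.55, 1.40 and 1.5, at 0 min not without the library labelled 0 min replicate 2 (1.20, adjusted p = 0.0907). Medians were 2.14, 2.35, 2.88, 2.83 and 2.85, and camera gave adjusted p = 4.52e-15, 1.21e-11, 8.75e-16, 2.30e-15 and 3.38e-15 (adjusted p = 0.185, 0.298, 0.188, 0.247 and 0.278 with an estimated correlation).

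Of 14 genes of formate metabolism, 5, 10, 12, 12 and 10 rose in order of time (10, 14, 12, 12 and 12 over the list alone) and none fell. SO_4513 rose by 4.98, 5.66, 5.46, 5.39 and 5.34, and pflB, which makes formate from pyruvate, stood at 2.75 ± 0.44 at 15 min. Much of that size comes from replicate 3, at 13112 CPM against 2875.2 and 4390.9 in the other 2. It was 1.85 (still passing) without that library, and a fit of only these 2 groups gave adjusted p = 0.0512. The pflB call at 30 min (1.65 ± 0.42) was lost without control replicate 1 (1.63, adjusted p = 0.0552). Medians were 0.76, 1.39, 1.07, 1.17 and 1.23 and camera adjusted p = 1.49e-06, 5.70e-07, 1.46e-06, 8.26e-07 and 3.85e-06 (adjusted p = 0.341, 0.320, 0.404, 0.324 and 0.389 with an estimated correlation). In the lactate list (5 genes) 1, 5, 2, 3 and 2 rose (2, 5, 4, 4 and 4 over the list alone), all 5 only at 15 min. SO_1522 rose by 2.10, 3.00, 2.41, 2.45 and 2.41 over the 5 times, and SO_1519 by 3.60 ± 0.75 at 15 min, where replicate 3 was above replicate 1 by a list median of 2.94. List medians were 1.21, 3.10, 1.74, 1.84 and 1.91 and camera adjusted p = 0.00837, 0.000233, 0.00502, 0.00426 and 0.00539 (adjusted p = 0.504, 0.320, 0.447, 0.421 and 0.455 with an estimated correlation).

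Of the 12 genes of the 2 Nqr complexes, 3, 6, 6, 6 and 6 rose and 0, 1, 1, 1 and 1 fell in order of time (6, 6, 6, 6 and 6 and 0, 1, 2, 2 and 2 over the list alone). The genes that rose lie side by side: SO_0902 rose by 2.44, 2.78, 2.65, 2.60 and 2.48 and SO_0903 by 2.27, 2.74, 2.69, 2.61 and 2.56. SO_0904 rose by 2.58, 2.65, 2.62 and 2.53 from 15 min on. camera adjusted p was 0.0110, 0.0483, 0.0473, 0.0526 and 0.0711 (adjusted p = 0.180, 0.298, 0.188, 0.247 and 0.307 with an estimated correlation). Its 0 min call was lost without control replicate 1 (0.0554), and those at 15 and 30 min in 9 of 16 fits each, up to 0.143 and 0.125. At 15 min it was kept without control replicate 3, 0 min replicate 1, the library labelled 0 min replicate 2, 15 min replicate 3, the library labelled 15 min replicate 2 or 45 min replicate 1 or 2. At 30 min it was kept without control replicate 3, 0 min replicate 1, the library labelled 0 min replicate 2, the library labelled 15 min replicate 2, 30 min replicate 3 or 60 min replicate 1 or 3. At 45 min the Nqr list was called without control replicate 3 (0.0430), 0 min replicate 1 (0.0284), the library labelled 0 min replicate 2 (0.0288), the library labelled 15 min replicate 2 (0.00712) or 45 min replicate 3 (0.0165). At 60 min the same held without 0 min replicate 1 (0.0429), the library labelled 0 min replicate 2 (0.0397), the library labelled 15 min replicate 2 (0.0140) or 60 min replicate 3 (0.0316). Medians were 0.84, 1.10, 1.04, 1.01 and 0.98.

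ATP synthase genes rose by less than 2-fold: 0, 8, 9, 8 and 1 of 9 passed in order of time, and all 9 at each time over the list alone. SO_4754 (0.68 ± 0.19 at 30 min) passed there except without control replicate 1 (0.62, adjusted p = 0.0860), control replicate 2 (0.63, adjusted p = 0.0833), 30 min replicate 1 (0.66, adjusted p = 0.0623) or 30 min replicate 2 (0.65, adjusted p = 0.0641). List medians were 0.65, 0.73, 0.74, 0.70 and 0.65 and camera adjusted p = 0.00203, 0.00296, 0.00462, 0.00705 and 0.0172 (adjusted p = 0.585, 0.601, 0.530, 0.658 and 0.609 with an estimated correlation). At 60 min that call was lost without control replicate 1 (0.0765), 15 min replicate 3 (0.0772) or 60 min replicate 1 (0.129). No gene of the 13 in the Nuo complex passed, over all genes or over the list (medians 0.34, 0.10, 0.09, 0.13 and 0.02; camera 0.128, 0.837, 0.857, 0.685 and 0.694). The Nuo list was called higher at 0 min without control replicate 2 (0.0286) or 3 (0.0368). At 60 min its mean and its camera direction were below 0 while its median was above.

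Flagellar genes (55 tested) rose at 0, 20, 9, 9 and 6 members in order of time, and 0, 24, 5, 5 and 27 rose over the list alone. Their medians were 0.18, 0.42, 0.37, 0.37 and 0.49. The chemotaxis gene cheY rose by 0.71, 0.79 and 0.88 from 30 min on, and fliE by 0.96 ± 0.16 at 15 min. The flagellin gene SO_3237 never passed (0.36, 0.77, 1.05, 1.08 and 1.31), though it did at 30, 45 and 60 min without 15 min replicate 3 (1.05, adjusted p = 0.0494; 1.08, adjusted p = 0.0415; 1.31, adjusted p = 0.0290) and at 60 min without 30 min replicate 3 (1.31, adjusted p = 0.0495). Its neighbour SO_3238 passed only at 15 min (0.66 ± 0.20), a call lost in 5 of 16 fits, without control replicate 1, 2 or 3, 15 min replicate 3 (adjusted p = 0.15) or 45 min replicate 1. camera called the list from 15 min on (adjusted p = 0.180, 7.77e-05, 0.00272, 0.000956 and 4.06e-05 over the 5 times; adjusted p = 0.834, 0.625, 0.749, 0.708 and 0.609 with an estimated correlation). The 30 min call was lost without 30 min replicate 3 (0.0903).

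Pilus genes did not pass. None of 11 type IV pilus genes did, over all genes or the list alone (medians 0.00, 0.02, 0.04, 0.11 and 0.21; camera 0.859, 0.912, 0.857, 0.680 and 0.416). The key genes SO_0417 (0.33, 0.12, 0.24, 0.28 and 0.22) and SO_4105 (0.09, 0.13, 0.16, 0.22 and 0.23) stayed within 0.33 of the control. At 0, 15 and 30 min camera placed the pilus list below the other genes, with a mean of 0.02 at each. None of the 14 mannose-sensitive pilus genes passed either (medians 0.05, -0.06, -0.15, -0.10 and -0.11; camera 0.568, 0.663, 0.263, 0.466 and 0.416). At 0 min their median was above 0 and their mean, -0.02, and camera direction below. In the mxd biofilm list (4 genes) SO_4179 alone fell, at 60 min (-0.39 ± 0.13), a call lost in 10 of 16 fits (adjusted p up to 0.272) and kept without 0 min replicate 1, the library labelled 0 min replicate 2, 15 min replicate 1 or 3, the library labelled 15 min replicate 2 or 30 min replicate 3. Over the list alone 1 gene fell at 45 and 60 min. Medians were -0.12, -0.13, -0.22, -0.06 and -0.11 (camera 0.362, 0.407, 0.226, 0.447 and 0.345).

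**Figure D4:**
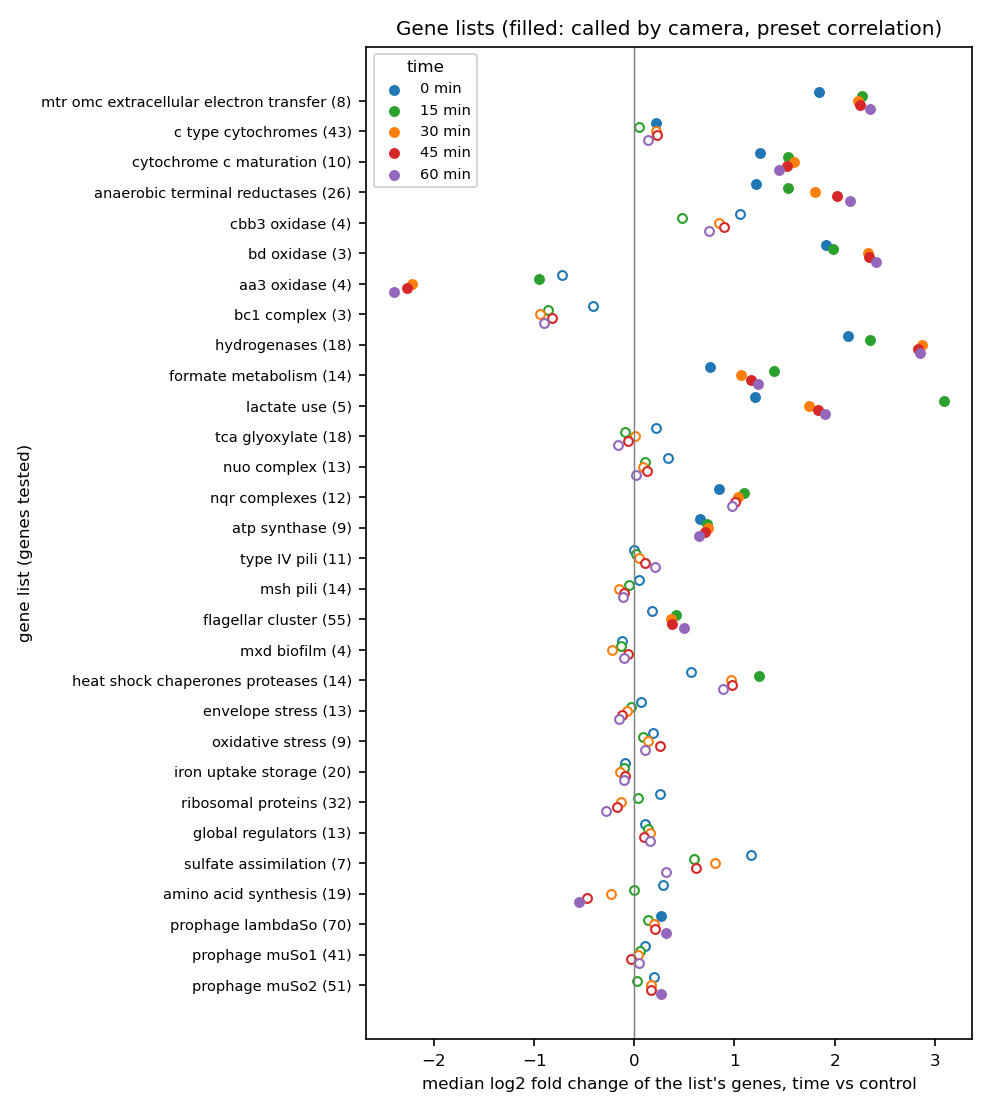
Median log2 fold change against the control (horizontal axis) of 30 gene lists (vertical axis, number of genes tested in brackets) at 5 times (colours); filled points were called by camera with its preset correlation. The hydrogenase list lies at 2.14 to 2.88 and the aa3 oxidase list at -2.40 at 60 min.

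Of 14 heat shock and protease genes, 0, 4, 1, 2 and 0 rose in order of time and none fell (0, 8, 0, 0 and 0 over the list alone), with medians of 0.56, 1.24, 0.96, 0.98 and 0.88. clpB rose by 2.05 ± 0.60 at 15 min, a call lost without control replicate 1 (2.07, adjusted p = 0.0918), 2 (2.0, adjusted p = 0.0877) or 3 (2.08, adjusted p = 0.0804), or without 15 min replicate 3 (1.10, adjusted p = 0.196). dnaK stood at 984.9 to 1158.6 CPM in the controls. In replicate 1 it went from 2388.7 at 15 min to 3065.4, 4163.7 and 4652 CPM at 30, 45 and 60 min. Replicate 2 had 1916.4, 3223.3 and 3911.8 CPM at 15, 30 and 45 min. Replicate 3 instead fell from 7026.3 to 2924, 1445.6 and 1232.6 CPM. dnaK passed only at 15 min (1.81 ± 0.56) and lost that call in 8 of 16 fits (edgeR adjusted p up to 0.245, without 15 min replicate 3). The call was kept without 0 min replicate 1, the library labelled 0 min replicate 2, 15 min replicate 1, the library labelled 15 min replicate 2, 30 min replicate 3, 45 min replicate 3 or 60 min replicate 1 or 3. At 30, 45 and 60 min dnaK did not pass (1.51, 1.56 and 1.45) but did in 3, 5 and 1 of 16 fits, among them that without 15 min replicate 3 (adjusted p = 0.0259, 0.0212 and 0.0432). groL never passed (0.26, 0.95, 0.44, 0.40 and 0.34). camera called the list at 15 min only (adjusted p = 0.342, 0.0401, 0.107, 0.159 and 0.310 over the 5 times; adjusted p = 0.828, 0.642, 0.749, 0.755 and 0.767 with an estimated correlation). That call was lost without control replicate 2 (0.0589), 15 min replicate 3 (0.324) or 30 min replicate 3 (0.0555). The list was called at 30 min without 60 min replicate 1 (0.0461) or 3 (0.0473), at 45 min without 45 min replicate 3 (0.00922) and at 60 min without 60 min replicate 3 (0.00176). Without all 5 libraries of replicate 3 it was called at 0, 30, 45 and 60 min (0.0477, 0.000416, 5.88e-06 and 4.72e-07).

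In the envelope stress list (13 genes) surA alone fell, at 45 and 60 min (-0.59 ± 0.17 and -0.68 ± 0.20), in each case lost in 4 of 16 fits (adjusted p up to 0.106 and 0.246). Those fits left out control replicate 1, control replicate 2 or a library of the time itself, and none fell over the list alone. Its medians were 0.07, -0.03, -0.07, -0.12 and -0.15 (camera 0.859, 0.944, 0.857, 0.466 and 0.267). At 15 and 30 min the means, 0.09 and 0.06, were above 0 while camera placed it lower. Without 60 min replicate 1 camera called it lower at 60 min (0.0239). Of 9 oxidative stress genes, 2, 3, 3, 3 and 3 rose and 0, 1, 2, 2 and 1 fell (2, 3, 4, 5 and 3 and 0, 1, 3, 3 and 2 over the list alone). oxyR, the peroxide-sensing regulator gene, rose by 1.90, 2.29, 2.02, 1.87 and 1.81, and katG, for a catalase, by 1.37, 1.41 and 1.38 from 30 min on. List medians were 0.18, 0.09, 0.13, 0.26 and 0.11 (camera 0.190, 0.475, 0.296, 0.346 and 0.345).

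Iron genes (20 tested) rose at 0, 3, 1, 3 and 2 members and fell at 1, 2, 3, 4 and 3 in order of time (0, 3, 1, 3 and 2 and 2, 5, 2, 5 and 3 over the list alone). The iron storage gene bfr (SO_1111) fell (-1.02, -1.10, -1.20, -1.16 and -1.06) over the 5 times. At 0 min it did not pass without control replicate 2 (-0.96, adjusted p = 0.0509), 0 min replicate 1 (-1.02, adjusted p = 0.0910) or the library labelled 0 min replicate 2 (-1.03, adjusted p = 0.155). At 60 min it did not pass without 60 min replicate 1 (-0.90, adjusted p = 0.0784). The second bfr gene (SO_1112) fell (-1.05 and -0.96) at 30 and 45 min. Medians were -0.09, -0.11, -0.14, -0.09 and -0.11 (camera 0.187, 0.245, 0.270, 0.346 and 0.345).

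Among 13 global regulators, 3, 5, 5, 5 and 5 rose and 0, 2, 2, 1 and 1 fell (3, 5, 5, 5 and 6 and 2, 3, 3, 3 and 2 over the list alone). SO_1329 rose by 0.85, 1.00, 1.03, 0.97 and 1.01, and crp by 1.66, 1.40 and 1.28 at 15, 30 and 45 min. At 0 min crp (1.23 ± 0.27) did not pass without control replicate 1 (1.12, adjusted p = 0.0571) or the library labelled 0 min replicate 2 (1.11, adjusted p = 0.149). At 60 min (1.25 ± 0.27) crp did not pass without 60 min replicate 1 (1.17, adjusted p = 0.0528). arcA, whose product answers to the redox state of the cell, passed at 30 min (0.91 ± 0.20) in every fit and at 15 min (0.81 ± 0.20) in all but that without 15 min replicate 3 (0.56, adjusted p = 0.0505). Its calls at 45 and 60 min (both 0.68) were lost in 5 and 13 of 16 fits (adjusted p up to 0.0830 and 0.182), that at 60 min being kept only without 15 min replicate 3, the library labelled 15 min replicate 2 or 30 min replicate 3. etrA fell at 15 min only (-0.33 ± 0.10), a call lost in 6 of 16 fits (adjusted p up to 0.137), without control replicate 1 or 2, 15 min replicate 1, the library labelled 15 min replicate 2 or 45 min replicate 1 or 2. It also passed at 0 min without 15 min replicate 3 (-0.38, adjusted p = 0.0391) and at 30 min without control replicate 3 (-0.36, adjusted p = 0.0440) or 15 min replicate 3 (-0.29, adjusted p = 0.0339). List medians were 0.11, 0.14, 0.16, 0.09 and 0.16 (camera 0.362, 0.356, 0.263, 0.382 and 0.345).

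Amino acid synthesis genes (19 tested) rose at 0, 0, 5, 2 and 0 members and fell at 0, 0, 4, 5 and 8 in order of time (0, 0, 6, 6 and 1 and 0, 0, 5, 10 and 12 over the list alone). Those that rose all lie in the tryptophan cluster SO_3019 to SO_3024. Those that fell are arginine and histidine genes: argB fell (-1.60 ± 0.36) and SO_0277 (-1.57 ± 0.37) at 45 min. Medians were 0.29, 0.00, -0.23, -0.47 and -0.55, and camera called the list lower at 60 min (adjusted p = 0.212, 0.753, 0.263, 0.0742 and 0.00795 over the 5 times; at 60 min adjusted p = 0.609 with an estimated correlation). At 45 min it was called lower without control replicate 1 (0.0412) or the library labelled 15 min replicate 2 (0.0333). At 15 min its median (just below 0) and camera direction differed from its mean, 0.01. In the ribosomal list (32 genes) nusG alone fell, at 45 min (-0.44 ± 0.15), a call lost in 14 of 16 fits and kept only without 15 min replicate 3 or the library labelled 15 min replicate 2. None moved over the list alone (medians 0.25, 0.03, -0.13, -0.18 and -0.28; camera 0.342, 0.835, 0.226, 0.225 and 0.0644). At 15 min the camera direction of this list was below 0 while its median and its mean, 0.04, were above. It was called lower at 30 min without 30 min replicate 2 (0.0217), at 45 min without control replicate 1 (0.0412), and at 60 min without control replicate 1 (0.00896) or 60 min replicate 1 (0.0259). None of 7 sulfate assimilation genes passed, over all genes or the list (medians 1.17, 0.60, 0.81, 0.62 and 0.32; camera 0.162, 0.837, 0.471, 0.605 and 0.976).

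In the list for the citric acid and glyoxylate cycles (18 genes) 1, 0, 2, 2 and 0 rose and 0, 1, 0, 0 and 0 fell (0, 0, 2, 2 and 0 and 0, 0, 0, 0 and 0 over the list alone). aceB, for malate synthase, rose at 30 min (1.95 ± 0.49) in every fit, and at 0 and 45 min (1.88 and 1.68) in calls lost in 12 and 5 of 16. Its 0 min call was kept only without 0 min replicate 1, 15 min replicate 1 or 3 or the library labelled 15 min replicate 2. Its 45 min call was lost without any 1 control, 45 min replicate 1 or 45 min replicate 2. Medians were 0.21, -0.10, 0.01, -0.06 and -0.16 (camera 0.463, 0.245, 0.779, 0.739 and 0.416). At 30 and 45 min the means, 0.11 and 0.08, lay above 0 while camera placed the list lower. Without 15 min replicate 1 it was called lower at 15 min (0.0158). Prophage genes moved in small numbers: in lambdaSo (70 genes) 5, 1, 7, 4 and 8 rose and 0, 1, 1, 1 and 0 fell (14, 0, 6, 3 and 5 and 0, 0, 0, 0 and 0 over the list alone; medians 0.26, 0.14, 0.20, 0.21 and 0.31). camera called it higher at 0 and 60 min (adjusted p = 0.00203, 0.479, 0.126, 0.228 and 0.0122 over the 5 times; 0.630 and 0.609 at these times with an estimated correlation). At 0 min it was not called without the library labelled 0 min replicate 2 (0.0563), and at 60 min not without control replicate 3 (0.0540), 15 min replicate 3 (0.0772) or 60 min replicate 3 (0.0537). Without control replicate 1 lambdaSo was called at 15, 30 and 45 min too (0.0263, 0.00162 and 0.00768), and without 30 min replicate 2 at 30 min (0.0211). In muSo1 (41 genes) 1, 1, 2, 2 and 2 rose and 0, 1, 3, 3 and 0 fell (1, 1, 1, 0 and 2 and 0, 0, 1, 0 and 0 over the list alone; medians 0.11, 0.06, 0.03, -0.04 and 0.05; camera 0.393, 0.837, 0.857, 0.787 and 0.814). Its camera direction was lower at 30 and 45 min against means of 0.00 and -0.01. In muSo2 (51 genes) 0, 1, 4, 2 and 2 rose and 0, 1, 1, 1 and 0 fell (0, 1, 2, 1 and 1 and 0, 0, 1, 0 and 0 over the list alone; medians 0.20, 0.03, 0.17, 0.16 and 0.27). Its camera call at 60 min (adjusted p = 0.104, 0.944, 0.268, 0.346 and 0.0139 over the 5 times; at 60 min 0.651 with an estimated correlation) was lost without control replicate 2 (0.0662), the library labelled 15 min replicate 2 (0.0536), 15 min replicate 3 (0.0772) or 60 min replicate 1 (0.0809). Without control replicate 1 muSo2 was called at 0, 30 and 45 min (0.000243, 0.0108 and 0.0155), and without 30 min replicate 2 at 30 min (0.0325). Across the 30 lists camera called 11, 12, 11, 10 and 13 in order of time. With an estimated correlation it called 0 at each time.

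Between neighbouring times the largest movement was that of SO_2407, which stood at 134 ± 7.30 CPM in the control, rose at 0 min (1.19 ± 0.31) and fell below it from 30 min on (-1.58 ± 0.29, -1.78 ± 0.30 and -1.99 ± 0.35). The libraries labelled 0 min lay far apart, at 424.4 CPM (replicate 1) and 186.1 CPM (replicate 2), so the size of that rise is uncertain. From 15 to 30 min (3 against 3) DESeq2 called 1 gene, a fit of only these 2 groups 0 and edgeR with the replicate number as a block 0. In the edgeR fit of all libraries without a block SO_2407 changed by -2.17 (adjusted p = 0.0295), the 1 gene to pass. That call was lost in 13 of 16 fits (adjusted p up to 0.332, without 30 min replicate 3) and kept only without 0 min replicate 1, the library labelled 0 min replicate 2 or 15 min replicate 1. Without the last of these the count was 3. From 0 to 15 min (2 against 3) no gene passed by edgeR, against 81 at unadjusted p below 0.05 and 0 by DESeq2, and 2 genes passed without 15 min replicate 1. From 30 to 45 min (3 against 3) no gene passed by edgeR, against 13 unadjusted and 0 by DESeq2. From 45 to 60 min (3 against 2) the numbers were 0, 23 unadjusted and 0 by DESeq2.

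From 0 to 60 min (2 against 2) SO_2407 changed by -3.19 (edgeR adjusted p = 0.00622), again the only gene, while DESeq2 called 22 (3 higher and 19 lower). It was lost without 60 min replicate 1 (-3.23, adjusted p = 0.256) or replicate 3 (-3.16, adjusted p = 0.30), and 2 genes passed without the library labelled 15 min replicate 2. In a fit of only these 2 groups no gene passed by edgeR, against 670 at unadjusted p below 0.05. A linear trend over the 13 libraries from 0 to 60 min was tested in 4492 genes, and SO_2407 alone passed, with a slope of -3.59 log2 units per hour (adjusted p = 0.0158). DESeq2 called 158 genes for the trend (55 rising, 103 falling) and edgeR with the replicate number as a block 13 (2 rising, 11 falling). By edgeR without a block 709 had an unadjusted p below 0.05. The slope did not pass without 0 min replicate 1 (-3.28, adjusted p = 0.163) or without 45 min replicate 1, 2 or 3 (-3.56, -3.56 and -3.54; adjusted p = 0.0618, 0.0601 and 0.0576). Without 15 min replicate 3 there were 48 genes with a trend, and without 60 min replicate 1 2.

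Over all 6 groups at once, with 16 libraries, 471 genes differed by the edgeR F-test, and cymA (adjusted p = 0.000819) was among them. The count was 170, 185 and 176 without control replicates 1, 2 and 3, 770 without the library labelled 15 min replicate 2 and 898 without 15 min replicate 3. Of 1308 genes that changed against the control at any time, 777 were higher, 532 lower and only SO_2407 both. ompW, hyaA, hyaB and cymA are among the 244 genes higher at all 5 times, 192 of them at least 2-fold each time, and SO_2850 and SO_0744 among the 25 lower at all 5. The 0 and 15 min comparisons shared 250 higher genes, against 34.7 for independent draws of the same size (n1 × n2 / N), and 37 lower genes against 2.23. All 5 comparisons use the same 3 controls, so part of this excess may come from them. In 20 simulations with no change but the same controls, only 0.05 genes were called per comparison and 0 were shared, so shared calls there cannot measure that part. The correlation of fold changes between 2 times was 0.386 to 0.491 in the simulations and 0.895 to 0.990 in the data, and the covariance 0.0287 to 0.0295 against 0.476 to 0.639.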

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

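The random draws and splits of libraries below were planned before the results were seen. The other tests in this part were chosen only after the patterns had been seen.

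SO_2407 was singled out because in the edgeR fit of all libraries it alone differed between groups taken from 0 min on. Other fits called other numbers: DESeq2 22 genes from 0 to 60 min and 158 for the trend, and edgeR 48 for the trend without 15 min replicate 3 and 276 without all of replicate 3. Fits of only the 2 groups called 0 both from 15 to 30 min and from 0 to 60 min. With the replicate number as a block there were 0 from 15 to 30 min and 13 for the trend. In the fit without a block SO_2407 changed by -2.17 from 15 to 30 min (edgeR adjusted p = 0.0295) and by -3.19 from 0 to 60 min (adjusted p = 0.00622). Its slope was -3.59 log2 units per hour over 0 to 60 min (adjusted p = 0.0158). For the trend, 3 of 100 arrangements of the times, the real order among them, gave as many genes (1 in the data, at most 1 in the others). With a count of 1 gene this says little beyond the edgeR adjusted p of SO_2407, and it leaves open which gene moves. The draws also take no account of libraries that may resemble each other by replicate number. For 30 against 15 min, 2 of 10 splits gave as many genes (1 in the data, 3 at most in the others), and the calls of SO_2407 depend on single libraries. Whether a decline of this transcript occurs in other cultures stays open.

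How the libraries are grouped was examined for the other counts. For 15, 30 and 45 min against the control, 1 of 10 splits each reached the real count (849, 964 and 1051 genes), and that was the real split, the others giving at most 0. The called lists were reached in 5 of 10 splits each (12 in the data and 17 at most at 15 min, 11 and 13 at 30 min, 10 and 15 at 45 min), and the other splits still hold part of the real contrast. For 45 against 30 min all 10 splits gave 0, and 10 splits are too few for a share under 0.05. For the 6 groups, 2 of 100 arrangements of the labels, the real grouping among them, gave as many genes (471 in the data, 472 in 1 other). That other draw happened to put all 3 controls in 1 group, while the 98 draws without this gave at most 31. This is consistent with a difference between control and later libraries, and says nothing about its cause; splits and draws take no account of libraries that may resemble each other by replicate number.

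The libraries labelled 0 min and 15 min of replicate 2 each lie beside the other time of replicate 1, and may have been exchanged. Their 15 minus 0 min differences correlate at -0.709 with those of replicate 1 across genes, which restates that position and is no separate evidence for an exchange. After thinning to 9795910 counts in 4361 genes, without the abundant RNAs, the correlation was -0.713. A shift common to all genes leaves such a correlation unchanged, so this cannot decide on library size or abundant RNAs. For a faster or slower passage through the same states a mark was set after the pattern had been seen. The distance to the control mean at 15 minus 0 min is -14.8, and the distances of the 3 controls to that mean span 4.84. This restates where the 2 libraries lie, and the controls lie 13.3 to 23.1 from each other, so it does not decide on such a passage. An exchange, a response in this culture that turned back, or a mix-up at sampling rather than at sequencing, stays open.

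Replicate 3 differs from replicate 1 at 15 to 60 min by an SD across genes of 0.594, 0.501, 0.429 and 0.382. A fixed offset as the whole cause, as a library batch would give, is argued against. The 15 and 60 min differences correlate at only 0.126, while those of neighbouring times correlate at 0.698 to 0.757. After thinning at least 100.1% of the SD was left. A shift common to all genes leaves this SD unchanged, so thinning cannot decide on library size. A larger response in the same direction could account for part of the 15 min difference (correlation with the response of replicate 1 0.521). The lactate genes lay above replicate 1 there (median 2.94, 0 of 5 below 0). The cbb3 oxidase genes went the other way (median -1.77, 4 of 4 below 0). Of these, ccoN stood at 702.8 CPM against 2299.4 in replicate 1 and 768.5 to 1286.1 in the controls. A larger response can neither be kept nor dropped at 30 min (0.314). At 45 and 60 min the correlation was 0.0418 at most. Replicate 1 enters both sides with opposite signs, and its later libraries resemble each other, which lowers these values. A larger response is therefore not decided at 45 and 60 min. Also open is a difference in this culture, or a cause in sampling or handling, that changes over the hour. The change may be in size or, as in the heat shock list (1.51 at 15 and -1.45 at 60 min), in direction.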

How the results depend on the processing

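No named gene that was called in the main fit or in the alternative reversed direction between them. Changes of sign in genes called in neither were not counted. RLE scaling, the absence of a filter, removal of rRNA and tRNA genes and robust = FALSE moved no count by more than 1.5-fold. ompW, hyaA, hyaB, cymA and SO_A0155 kept their calls at all 5 times in every fit that left out 1 library. Of the genes named at 0, 15, 30, 45 and 60 min against the control, 26 of 50, 55 of 80, 61 of 88, 59 of 89 and 41 of 76 calls were kept in every such fit. Where counts moved the cause was not tested. Fits of 1 library against 3 or of 2 groups hold fewer samples. Even so, fits of 2 groups gave more genes against the control at 0 min (503, from 299) and at 60 min (1338, from 839).

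With DESeq2 543 genes changed at 0 min (410 higher, 133 lower) and 1319 at 60 min (776 and 543) against the control, 22 from 0 to 60 min, 1152 over the 6 groups and 158 with the trend, all by more than 1.5-fold from edgeR, and the cause was not tested. With the replicate number as a block there were 523 genes at 0 min (376 higher, 147 lower), 0 from 15 to 30 min (SO_2407 -2.17, adjusted p = 0.124), 749 over the 6 groups and 13 with the trend. Correlations of libraries that share a replicate number after removal of group means run from -0.637 to 0.785 (median 0.079, against -0.0309 for other pairs), and 8 of 16 libraries resemble their own number most. From 15 to 60 min same-number pairs lie at 0.175 to 0.672 (replicate 1), 0.356 to 0.548 (replicate 2) and 0.079 to 0.785 (replicate 3). The later libraries thus do resemble their number (0.383, 0.489 and 0.733 between 15 and 30 min). Pairs of replicates 1 and 2 also reach 0.623. Removal of group means pushes replicates 1 and 2 together where replicate 3 stands apart, so that value cannot weigh against pairing. Same-number values of replicates 1 and 2 are raised in the same way. Same-number pairs of a control lie at -0.0917 to 0.144, and those with a 0 min library include the 2 that may be exchanged. The short names of the libraries begin alike within a replicate number, without a stated meaning. As not every pair exceeds 0.1 and the labels state no pairing, the numbers were not taken to pair the libraries, which leaves open that the later ones come from shared cultures. In fits of only the 2 groups compared, 503 genes passed at 0 min (406 higher, 97 lower), 249 at 15 min (224 and 25) and 1338 at 60 min (768 and 570) against the control, and 0 both from 15 to 30 min and from 0 to 60 min.

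Leaving out 1 library gave 112 (without the library labelled 0 min replicate 2) to 520 genes (without 15 min replicate 3) at 0 min against the control, 488 to 1253 at 15 min, 571 to 1349 at 30 min, 648 to 1435 at 45 min and 346 to 1340 at 60 min. From 0 to 15 min the range was 0 to 2, from 15 to 30 min 0 to 3, from 30 to 45 and from 45 to 60 min 0 to 0, from 0 to 60 min 0 to 2, over the 6 groups 170 to 898 and for the trend 0 to 48. A 60 min or 0 min library left alone was tested with the spread of the other groups. The cause was not tested.

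Lists called went from 11, 12, 11, 10 and 13 at the 5 times to 0 each time once camera estimated the correlation per list. With fry, which asks whether a list moved in 1 direction, they were 10, 14, 14, 13 and 16. Its form for changes in either direction gave 12, 13, 16, 16 and 15. Leaving out 1 library gave 10 to 12, 9 to 13, 10 to 13, 10 to 14 and 10 to 14. The Mtr and Omc, cytochrome c maturation, anaerobic reductase, bd oxidase, hydrogenase, formate and lactate lists kept their camera call in every such fit at every time. With the block the aa3 oxidase, Nqr and heat shock calls at 15 min and the Nqr call at 30 min were lost (adjusted p = 0.0815, 0.104, 0.0952 and 0.107), while the flagellar list at 0 min (0.0151) and amino acid synthesis at 45 min (0.0429) were gained. RLE lost the Nqr call at 15 min (adjusted p = 0.0528).

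The following sets were chosen only after the data had been seen. Without the 5 libraries of replicate 3 there were 514 genes at 0 min, 513 at 15 min, 0 both from 15 to 30 min and from 0 to 60 min, and 276 with the trend. Lists then gained were heat shock at 0, 30, 45 and 60 min (adjusted p = 0.0477, 0.000416, 5.88e-06 and 4.72e-07), cbb3 oxidase at 0, 15, 30 and 45 min (0.00243, 0.0189, 0.00237 and 0.00523), sulfate assimilation at 0 and 30 min (0.04998 and 0.0237), ribosomal genes, higher, at 15 min (0.0463) and c-type cytochromes at 45 min (0.0276). Lists lost were Nqr at 0 and 30 min (0.0544 and 0.0670), aa3 oxidase at 15 min (0.225), the flagellar list at 30 min (0.0932), lambdaSo at 0 and 60 min (0.229 and 0.521) and muSo2 at 60 min (0.186). Without the 2 libraries labelled 0 min and 15 min of replicate 2 there were 194 genes at 0 min, 3 from 0 to 15 min and 22 from 0 to 60 min. Nqr at 45 and 60 min (0.000193 and 0.000496) and amino acid synthesis at 45 min (0.0258) were gained. c-type cytochromes and lactate at 0 min (0.0888 and 0.0550), heat shock at 15 min (0.0678), ATP synthase at 60 min (0.0657), lambdaSo at 0 and 60 min (0.177 and 0.0573) and muSo2 at 60 min (0.0847) were lost. The cause was not tested. Depth sets a floor of 0.168 to 0.207 CPM for 3 reads, from counting error alone, and in simulated data 1.5-fold changes were recovered in 11.9 to 40.3% of genes in comparisons of 2 groups.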

Other observations

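Of the 244 genes higher at all 5 times, 35 lie in 7 runs of at least 4 neighbouring genes (among 4351 genes with a position), and the fixed lists hold these runs only in part. The largest rises are in SO_A0153 to SO_A0158 on the plasmid (6 genes, median log2 fold change 5.46, range 3.00 to 7.15) and SO_4593 to SO_4598 (5 genes, 4.92, range 3.16 to 6.01). Libraries of a time differed widely in the plasmid run. SO_A0153 at 15 min stood at 7620.9, 143.7 and 21335 CPM in replicates 1, 2 and 3, against up to 131.2 in a control. SO_0396 to SO_0399 (4 genes) had a median of 3.50. SO_4199 to SO_4204 (6 genes, 1.52) includes ubiE and ubiB, which make ubiquinone, and tatA, tatB and tatC, which export folded proteins. SO_0138 to SO_0142 (4 genes, 0.87) includes moeA, for the molybdenum cofactor, and ftnA, for iron storage. The remaining 2 runs are the hydrogenase genes SO_2089 to SO_2093 (3.47) and SO_2095 to SO_2099 (4.02). These runs were looked for after the results had been seen and were not tested.

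Between 0 and 60 min no member of the lists below passed in the edgeR fit of all libraries (DESeq2 called 22 genes), but camera with its preset correlation called 10 lists (a comparison added after the data had been seen). The median log2 change of amino acid synthesis genes was -0.77 (adjusted p = 1.38e-13), that of ribosomal genes -0.47 (adjusted p = 1.98e-07) with 0 of 32 above 0, and that of aa3 oxidase genes -1.60 (adjusted p = 0.000655). Sulfate assimilation, with a median of -0.76 (adjusted p = 0.0492), Nuo, -0.32 (adjusted p = 0.00154), the citric acid and glyoxylate list, -0.38 (adjusted p = 0.0147), and envelope stress, -0.27 (adjusted p = 0.0151), also had medians below 0. The medians above 0 were those of anaerobic reductase genes, 0.81 (adjusted p = 5.08e-06), hydrogenase genes, 0.46 (adjusted p = 0.00154), and flagellar genes, 0.25 (adjusted p = 9.93e-08) with 55 of 55 above 0. None of these was called with an estimated correlation (adjusted p = 0.285 for amino acid synthesis and 0.830 for the others), and the 4 libraries include 60 min replicate 3, which stands apart, and the library labelled 0 min replicate 2, which may be exchanged (without it and the library labelled 15 min replicate 2, 22 genes passed).

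In replicate 3 minus replicate 1, list medians at 15, 30, 45 and 60 min were -2.32, -2.31, -1.65 and -1.20 for sulfate assimilation, -0.75, -0.70, -0.65 and -0.17 for ribosomal genes, -1.43, -0.98, -0.59 and -0.12 for the citric acid and glyoxylate list and 0.52, 0.37, 0.20 and 0.01 for flagellar genes. With 1 library on each side these differences were not tested. The control libraries held more aligned reads assigned to no gene than all others, 53.4 against 52.6% on average (difference 0.753 points, 3 against 13 libraries). The lowest control, 53.2%, was above the highest other library, 53.1%. Whether such reads lie outside genes or on their opposite strand is not known. The exact two-sided permutation p of 0.00179 over 560 splits restates that order and takes the 13 other libraries as exchangeable, which libraries of 5 times are not known to be.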
